A study of Escherichia coli with 6 samples.

How the data were processed

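RNA was measured in 6 libraries of Escherichia coli DH5alphaZ1 carrying the plasmid p24KmNB82. DH5alphaZ1 is a laboratory K-12 strain with a recA allele that abolishes recombination, a gyrA allele that gives resistance to nalidixic acid, a deletion of the chromosomal argF-lacZ interval and chromosomal copies of the lac and tet repressor genes. Per the labels' protocols, stationary cultures were diluted 100-fold into fresh MMB+ medium, a defined medium with glycerol, amino acids and kanamycin. The group amp_24h holds 3 libraries from cultures kept with 0.1 mg/mL ampicillin for 24 h, and the group cip_6h holds 3 libraries from cultures kept with 10 µg/mL ciprofloxacin for 6 h. Samples were filtered, lysed in the presence of chloramphenicol, depleted of rRNA with RiboMinus and made into NEBNext Ultra II libraries for paired-end Illumina sequencing, per the labels' protocols. The groups differ in both drug and time, so no comparison here separates the drug from the time, and untreated or earlier samples were not analysed here.

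The authors deposited 1 table of expected or estimated counts per coding sequence, not scaled to depth. Of its values, 59.4% were whole and 99.5% were whole or a half-integer within a tolerance of 0.001, as arises when a read matching several genes is shared between them. The aligner, the counter, the genome build and any filter are not given in the sources used here. The table has 4359 rows, and its rows are coding sequences, with no rRNA or tRNA among them. The 2 coding sequences listed a second time under the same locus tag were summed with their first listing, which left 4357 genes. Locus tags of 4351 genes matched the RefSeq gene table of assembly ASM584v2 (strain MG1655), which was used only for names, gene type and gene order, and 6 did not match. The 2 rows without a locus tag, Km and cfp, carry the names of a kanamycin resistance gene and a cyan fluorescent protein gene. All 6 deposited columns were mapped to samples by their names.

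The expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), which left 4142. Library sizes were scaled by TMM, and amp_24h was compared with cip_6h by the quasi-likelihood test (glmQLFit with robust dispersion, glmQLFTest). Log2 fold changes are amp_24h minus cip_6h with their standard errors (SE), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every adjusted p given for a gene comes from this edgeR test unless another is named. Normalised read counts are given as CPM, relative to the TMM-scaled library size. They stand as mean ± SD over the 3 libraries of a group. Before the data were examined, 42 gene lists, the tests, most alternatives and the rule for named genes were fixed. Lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided, and the p-values were adjusted over the 42 lists. Camera compares a list's genes with all other genes. It was repeated with the correlation estimated from the data, and fry, which tests a list against no change and not against other genes, was run beside it. The fixed lists hold 1133 different genes, of which 1067 were tested.

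The rule for named genes had 3 parts that applied. The first took, in each direction, the 6 protein-coding genes with the largest change among those past the threshold, with a mean CPM of at least 20 and no overlap between the groups. The next took from each list that passed the test the 2 members with the smallest adjusted p in the list's direction, and the member with the smallest adjusted p in the other direction if past the threshold. The last took 12 genes whatever their result: recA, lexA, sulA, tisB, gyrA, gyrB, ampC, mrcB, rpoS, rmf, hipA and acrB. Together these named 73 genes. The plasmid genes Km and cfp were added after their values were seen.

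Total counts were 3209161 to 3566499 per amp_24h library and 7852477 to 11451226 per cip_6h library, and the counts left after the plasmid genes were 1261155 to 1572439 and 4069096 to 5763078. The TMM factors were 1.17 to 1.77 in amp_24h and 0.613 to 0.761 in cip_6h. The median count per gene was 82 to 174 and 88 to 128. Replicates of a group differed by more than sampling noise in every pair (smallest chi-square per degree of freedom 9.42), so no library was counted as a duplicate. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

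The gene and list tests were tested on simulated counts made from the means and library sizes of these 6 libraries, over 4142 genes. Of the genes changed by 1.5-fold, 6.15% were recovered in the right direction, against 46.3% of those changed 2-fold and 87.9% of those changed 4-fold. Of 108 genes called, 2.78% were unchanged. With no change simulated, 1 gene was called. In the simulation with changed genes, 0 of 40 lists without a change were called. Genes were drawn independently, and fewer were changed than differed in the data. The simulation therefore does not test the preset correlation of camera on correlated genes. Both groups were simulated from the same gene proportions, apart from the changed genes. The share of unchanged genes among the calls therefore leaves out errors of the TMM scaling where many genes differ.

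The alternatives were RLE factors, library size only, upper quartile factors, no filter, a stricter filter (CPM of at least 10 in at least 3 samples), the replicate number as a block, limma-voom, DESeq2 1.42.0, no robust dispersion, a test against a 2-fold change (glmTreat), the estimated correlation, fry, and leaving out each replicate in turn. Leaving out the plasmid genes and thinning all libraries to the lowest chromosomal total were added after seeing the data. The comparison of called lists with random lists matched on level (each gene replaced by one within 50 ranks) was also added then. Leaving out rRNA and tRNA genes was planned but not run, because the table lists none. Genes with near-identical copies, such as those of the cryptic prophages and the paired toxin-antitoxin loci, share reads, and their counts are uncertain. Whether counting used the strand is not given in the sources used here, so reads from overlapping genes on opposite strands could not be told apart. Shares of counts were compared with a two-sided exact permutation test, which cannot go below 0.1 with 3 libraries against 3. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.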

Results

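RNA sequencing compared E. coli populations kept in ampicillin for 24 h with populations kept in ciprofloxacin for 6 h, with 3 libraries in each group. Ampicillin blocks the enzymes that cross-link the cell wall, and ciprofloxacin traps DNA gyrase and topoisomerase IV on DNA. The series concerns persisters, the cells of an isogenic population that outlive an antibiotic without a resistance mutation, and the comparison asks how the transcriptomes of the 2 treated populations differ. The amp_24h libraries held 3209161, 3566499 and 3377897 counts (replicates 1 to 3) and the cip_6h libraries 11451226, 7852477 and 7976184, so depth also differed between the groups.

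The amp_24h libraries held far less mRNA for the translation machinery, nucleotide synthesis and DNA gyrase than the cip_6h libraries, and more mRNA for the uptake of alternative carbon sources, the general stress response, capsule and the RpoE envelope response. The camera list calls behind this were made with a preset correlation, and all were lost with an estimated correlation (smallest adjusted p = 0.301). High correlation between genes is not the whole reason. The cryptic prophage list also lost its call, though its estimated correlation of -0.012 was below the preset 0.01. The RpoE call was also lost without amp_24h replicate 1 (adjusted p = 0.0872). The decreases of the lower lists did not exceed the central range of random lists of genes as abundant in cip_6h. The ribosomal protein list lay outside that range on the other side and fell less (median log2 fold change -2.37, random lists -3.42 to -2.53). This depended on the matching. Matched on the mean level of both groups, translation factors (0.11 percentile), nucleotide synthesis (1.49) and synthetases (2.22) lay in the lowest 2.5%. The gyrase and replication list (6.03) and ribosomal proteins (21.8) then lay inside the central range. The largest decrease in amp_24h was that of ydhR, at 24.3 ± 3.35 CPM against 1731 ± 114 CPM (71.5-fold lower, n = 3 per group). gyrA, which encodes the DNA-cutting subunit of gyrase, followed at 228 ± 58.7 against 9156 ± 349 CPM (40.2-fold lower), and then the neighbouring genes trmD, rimM and rpsP, which encode a tRNA methyltransferase, a ribosome maturation factor and a ribosomal protein, at 37.6-fold, 34.1-fold and 30.7-fold lower. yjeV was 29.6-fold lower. The largest increase was that of yjbE, from an exopolysaccharide operon, at 690.3 ± 728 against 6.14 ± 3.06 CPM (112-fold higher), with values of 1518, 399.6 and 153 CPM in amp_24h replicates 1, 2 and 3. pspG of the phage shock response was 69.7-fold higher, mntS, a small protein of manganese control, 35.8-fold, the stationary-phase ribosome protein gene sra 29.7-fold, ytfK 26.2-fold and the capsule gene wcaD 26.0-fold. The adjusted p of these 12 genes ranged from 3.7e-08 for ydhR to 0.00348 for yjbE. Without amp_24h replicate 1, the log2 fold change of yjbE was 5.29 in place of 6.81, that of wcaD 3.47 in place of 4.70 and that of ytfK 4.10 in place of 4.71. For pspG it was at least 5.71 over all alternatives, so the first rank of yjbE rested on amp_24h replicate 1. These ranks are among genes with a mean CPM of at least 20 and no overlap between the groups.

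Of 4142 genes tested, 1519 were higher and 1234 lower in amp_24h, and 1389 did not pass the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). At least 4-fold differences were found for 475 genes higher and 434 lower, and at least 16-fold differences for 38 and 44. The groups did not overlap at all for 68.7% of the genes, against 10% by chance. The split depended on the scaling. Of the changed genes, 55.2% were higher with TMM, 84.4% with library size only and 68.0% with upper quartile factors, and these scalings moved the median of all genes by 1.20 and 0.44 on the log2 scale, while RLE factors moved it by -0.17. Directions below are those with TMM, and any that another of these scalings turned is named.

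The distribution of counts over genes was flatter in amp_24h. The 100 most abundant chromosomal genes took 34.2 ± 4.17% of chromosomal counts in amp_24h and 56.1 ± 0.948% in cip_6h (n = 3 per group; exact permutation test, two-sided p = 0.1, the smallest this design allows), and the 10 most abundant took 8.96 ± 0.995% and 17.3 ± 0.880%. Among the 258 genes most abundant in cip_6h, 237 were lower in amp_24h, 1 was higher and the median log2 fold change was -2.66. Among the 192 genes below 2 CPM in cip_6h, 151 were higher, 0 were lower and the median was 2.03, a range of levels at which genes selected for a low cip_6h value also rise by chance. Because change followed level, each of the 20 called lists was compared, after the results were seen, with 10000 random lists matched on cip_6h level. Of the 9 higher lists, 6 lay in the highest 2.5% of these (carbon starvation, RpoS, capsule and Rcs, branched-chain amino acids, iron limitation and RpoE), as they did when matched on the mean level of both groups. The 3 others did not, with flagella at the 29.7, toxin-antitoxin at the 72.9 and cryptic prophage at the 1.83 percentile. Of the 11 lower lists, 0 lay in the lowest 2.5%. Matched on mean level, 3 did (synthetases at 2.22, purine and pyrimidine at 1.49 and translation factors at 0.11). Matched on cip_6h level, ribosomal proteins lay at the 99.35 and glycolysis at the 97.61 percentile, so both fell less than most genes of their level. On mean level these 2 lists lay at 21.8 and 87.2.

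**Figure D1:**
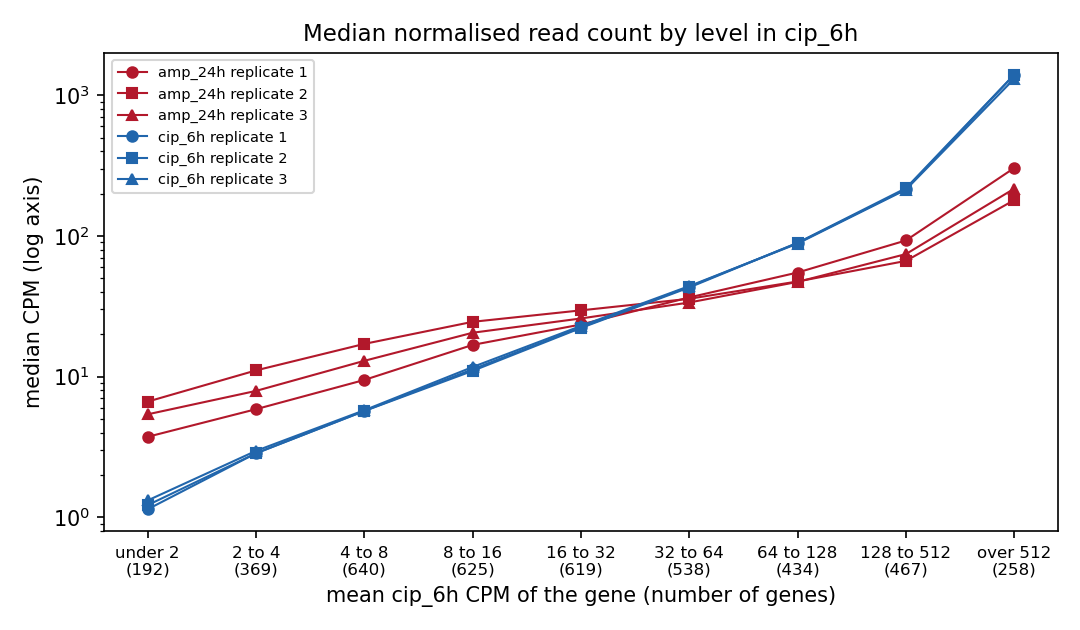
Median normalised read count (CPM, log axis) of genes grouped by their mean CPM in cip_6h, with the number of genes under each group; each line is 1 of the 6 libraries. In the group of highest level the cip_6h medians were 1307 to 1398 CPM and the amp_24h medians 179.5 to 304 CPM, and below 2 CPM they were 1.14 to 1.32 and 3.73 to 6.64 CPM.

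Genes for protein synthesis were lower in amp_24h almost throughout. Of 54 ribosomal protein genes, 53 fell, 0 rose and 1 did not pass the threshold (median log2 fold change -2.37), with rpsP 30.7-fold and rpmF 21.5-fold lower. Of 23 aminoacyl-tRNA synthetase genes, 22 fell and 1 did not pass (median -2.50), with aspS 25.0-fold and argS 23.8-fold lower. All 16 translation factor genes tested fell (median -2.90), among them rimM and the release factor gene prfC, which was 9.66-fold lower. Of 25 purine and pyrimidine biosynthesis genes, 23 fell, 1 rose and 1 did not pass (median -2.19). purK and purE, which act together on a purine intermediate, were 24.1-fold and 19.5-fold lower, and pyrC was 1.44-fold higher (adjusted p = 0.0495, lost without any library but amp_24h replicate 2, as 0.252 without amp_24h replicate 1, and between 1.1e-04 and 1.00 over all alternatives). These medians stayed below 0 with every scaling. Camera adjusted p-values were 4.9e-17 for ribosomal proteins, 7.6e-10 for the synthetases, 1.0e-07 for the factors and 5.2e-09 for nucleotide synthesis. No call held with an estimated correlation (adjusted p = 0.704 with an estimated correlation for ribosomal proteins and 0.617 for the other lists). Adjusted over the list alone, the counts in these lists were the same. Scaled by library size only, 2 rose and 43 fell among ribosomal protein genes, 2 and 18 among synthetases, 1 and 13 among factors and 2 and 17 in nucleotide synthesis. Of 19 genes for RNases and RNA turnover, 11 fell, 2 rose and 6 did not pass, with rph 10.5-fold and the RNase R gene rnr 8.14-fold lower and the RNase G gene rng 2.62-fold higher. The median was -0.98 with TMM and 0.14 with library size only, where 6 rose and 6 fell (camera adjusted p = 0.00678, and adjusted p = 0.704 with an estimated correlation). Adjusted over the list alone, the counts were the same.

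DNA gyrase, topoisomerase and replication genes were lower in amp_24h, in 25 of 31 genes, while 2 were higher and 4 did not pass (median -1.33, camera adjusted p = 2.2e-06; adjusted p = 0.321 with an estimated correlation; the same counts adjusted over the list alone). The counts were 7 higher and 11 lower with library size only, and the median was -0.11. gyrA had a log2 fold change of -5.33 ± 0.31 (SE, adjusted p = 4.7e-08) and gyrB, at 296 ± 45.9 against 2101 ± 73.8 CPM, one of -2.83 ± 0.24 (adjusted p = 4.6e-07). nrdA, a subunit of ribonucleotide reductase, was 23.4-fold lower, and polA, DNA polymerase I, was 1.92-fold higher. The SOS genes, which LexA represses, had no common direction with TMM. Whether they report DNA damage in this strain, with its mutant recA allele, was not tested. Of 31 SOS genes, 9 rose, 12 fell and 10 did not pass, also when adjusted over the list alone. Scaled by library size only, 19 rose and 3 fell. The median was 0.17 with TMM, -0.01 with RLE factors and 1.37 with library size only, the mean was -0.07, and camera placed the list lower with adjusted p = 0.554. recA was 6.30-fold lower in amp_24h (204 ± 68.3 against 1286 ± 97.2 CPM, adjusted p = 2.6e-06), and sulA, the SOS inhibitor of cell division, was 5.64-fold higher (65.0 ± 17.1 against 11.5 ± 2.23 CPM, adjusted p = 2.3e-06). lexA was 1.46-fold higher (log2 0.54 ± 0.19 SE, adjusted p = 0.0249) and the membrane toxin gene tisB 1.65-fold (0.73 ± 0.27 SE, adjusted p = 0.0296). Leaving out 1 library ended these last calls, for lexA without amp_24h replicate 1 or cip_6h replicates 1 or 2 (adjusted p = 0.242, 0.104 and 0.0997; 3.6e-05 to 1.00 over all alternatives) and for tisB without amp_24h replicates 1 or 3 or cip_6h replicates 1 or 3 (0.0698, 0.143, 0.0567 and 0.128; 2.0e-04 to 0.856 over all alternatives). Of 23 recombination and double-strand break repair genes, 4 rose, 11 fell and 8 did not pass (5 rose adjusted over the list alone; median -0.48, but 0.63 with library size only, where 13 rose and 4 fell; camera adjusted p = 0.131).

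Genes for carbon starvation and for sugar uptake under cAMP-CRP rose together. Of 46 tested, 42 were higher in amp_24h, 0 were lower and 4 did not pass (median 2.18, camera adjusted p = 1.6e-09; adjusted p = 0.301 with an estimated correlation; the same counts adjusted over the list alone). Scaled by library size only, 46 were higher and 0 lower. rbsB and rbsD, of ribose uptake, were 19.9-fold and 19.3-fold higher, at 574 ± 143 against 28.8 ± 3.34 CPM and 287 ± 30.3 against 14.7 ± 3.62 CPM. In the general stress list, under the sigma factor RpoS, 27 of 39 genes rose, 1 fell and 11 did not pass (median 1.88, camera adjusted p = 2.5e-04; adjusted p = 0.617 with an estimated correlation; the same counts adjusted over the list alone). In that list 35 rose and 1 fell with library size only. sra was 29.7-fold and uspB 11.3-fold higher, and xthA, exonuclease III, was 21.3-fold lower, at 27.4 ± 4.50 against 586 ± 423 CPM. Its genes lay a median of 0.56 (log2) higher in amp_24h replicate 1 than in the other amp_24h replicates. rpoS itself did not pass, at 1238 ± 570 against 1002 ± 44.8 CPM (log2 0.30 ± 0.30 SE, adjusted p = 0.385), though it was higher with library size only (1.8e-05) and upper quartile factors (0.0255) and ranged from 1.8e-05 to 1.00 over all alternatives. Without amp_24h replicate 1 its log2 fold change was -0.27 (adjusted p = 0.312). The ribosome hibernation factor gene rmf was 15.4-fold higher (1115 ± 898 against 72.6 ± 17.8 CPM, adjusted p = 5.1e-04), with a log2 fold change of 2.88 in place of 3.94 without amp_24h replicate 1. In the list of ribosome hibernation and stringent response genes, 3 of 12 rose and 9 fell, also adjusted over the list alone (median -1.29, camera adjusted p = 0.153). In this list 4 rose and 2 fell with library size only, with a median of -0.11.

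Envelope stress was covered by the RpoE, Rcs and Cpx lists. In the RpoE list, for misfolded outer membrane proteins, 16 of 25 genes rose, 4 fell and 5 did not pass (median 0.98, camera adjusted p = 0.0238; adjusted p = 0.704 with an estimated correlation; the same counts adjusted over the list alone). rseA, the anti-sigma factor gene, was 21.1-fold higher at 3027 ± 739 against 143 ± 6.32 CPM, rpoE 20.1-fold at 1128 ± 251 against 56.0 ± 6.57 CPM, and fabZ of fatty acid synthesis 4.42-fold lower. Without amp_24h replicate 1 the list's adjusted p was 0.0872, the highest over the alternatives apart from the estimated correlation, with a lowest of 0.00525. The RpoE counts were 22 higher and 1 lower with library size only. In the capsule and Rcs list, 25 of 32 genes rose, 2 fell and 5 did not pass (median 2.84, camera adjusted p = 4.3e-04; adjusted p = 0.704 with an estimated correlation; the same counts adjusted over the list alone). yjbG and yjbH were 15.2-fold and 6.75-fold higher and ymgG 12.3-fold lower. The genes of this list lay a median of 1.70 (log2) higher in amp_24h replicate 1 than in the other amp_24h replicates, and without that replicate the median log2 fold change was 2.00. The counts were 28 and 2 with library size only. In the Cpx list, 12 of 21 rose, 2 fell and 7 did not pass, also adjusted over the list alone (median 0.69, camera adjusted p = 0.0596), while 19 rose and 0 fell with library size only. This list passed with library size only (0.0140), upper quartile factors (0.0337), the stricter filter (0.0284), limma-voom (0.0338) and thinned libraries (0.0456), and without amp_24h replicate 2 (0.0204) or 3 (0.0486), and ranged from 0.0140 to 0.227 over the alternatives with the preset correlation (adjusted p = 0.704 with an estimated correlation).

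Among the cell wall lists, peptidoglycan hydrolysis and recycling genes were lower in 19 of 36 cases, higher in 6 and not past in 11 (median -0.65, but 0.57 with library size only; camera adjusted p = 0.0238; adjusted p = 0.617 with an estimated correlation; the same counts adjusted over the list alone). With library size only, 15 were higher and 4 lower, and the call was lost there (adjusted p = 0.256) and with the stricter filter (0.122). The amidase gene amiB was 7.48-fold and the transglycosylase gene emtA 3.94-fold lower, while ldtD, a transpeptidase that ampicillin does not block, was 4.47-fold higher. Of 23 cell division genes, 13 fell, 1 rose and 9 did not pass (median -0.79, but 0.36 with library size only; camera adjusted p = 0.00503; adjusted p = 0.704 with an estimated correlation; the same counts adjusted over the list alone). With library size only, 8 rose and 3 fell, and the call was lost (adjusted p = 0.129). zapA and ftsB were 7.01-fold and 4.25-fold lower, and the member that rose was sulA. Peptidoglycan synthesis genes did not pass as a list, with 5 of 27 higher, 12 lower and 10 not past, also adjusted over the list alone (median -0.27, but 0.93 with library size only and 0.17 with upper quartile factors; camera adjusted p = 0.190; 15 higher and 2 lower with library size only). mrcB, penicillin-binding protein 1b, had a log2 fold change of -0.76 ± 0.24 (SE, adjusted p = 0.0119) with TMM and 0.39 with library size only. The chromosomal beta-lactamase gene ampC had one of -0.67 ± 0.25 (SE, adjusted p = 0.0315) with TMM and 0.57 with library size only, and it did not pass without any 1 of the cip_6h replicates (adjusted p = 0.05002, 0.0704 and 0.117; 0.00579 to 0.943 over all alternatives). In the heat shock list, 16 of 25 fell, 4 rose and 5 did not pass (median -0.84, but 0.31 with library size only; camera adjusted p = 0.0287; adjusted p = 0.704 with an estimated correlation; the same counts adjusted over the list alone). The protease gene hslU and ybeZ were 4.39-fold and 3.93-fold lower, and ibpB, a small chaperone of aggregated proteins, was 12.6-fold higher. With library size only, 10 rose and 4 fell. The heat shock call was lost with library size only (adjusted p = 0.263), with the stricter filter (0.113) and without amp_24h replicate 2 (0.0619), and ranged from 0.0122 to 0.263 over the alternatives with the preset correlation.

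In metabolism, branched-chain amino acid biosynthesis rose, with 15 of 16 genes higher, 0 lower and 1 not past (median 1.25, camera adjusted p = 5.99e-04; adjusted p = 0.301 with an estimated correlation; the same counts adjusted over the list alone). All 16 were higher with library size only. ilvB, of acetolactate synthase, was 6.45-fold and ilvA, threonine deaminase, 2.63-fold higher. Glycolysis and gluconeogenesis genes were lower in 10 of 19 cases, higher in 2 and not past in 7 (median -0.75, but 0.45 with library size only; camera adjusted p = 0.0145; adjusted p = 0.704 with an estimated correlation; the same counts adjusted over the list alone). With library size only, 9 were higher and 6 lower, and the stricter filter ended the call (adjusted p = 0.0555). The enolase gene eno was 10.5-fold and lpd 9.29-fold lower, and fbp, of gluconeogenesis, 2.45-fold higher. In the Fur list of iron limitation genes, 29 of 51 rose, 6 fell and 16 did not pass (median 1.12, camera adjusted p = 0.00566; adjusted p = 0.704 with an estimated correlation; the same counts adjusted over the list alone). The Fur counts were 41 and 0 with library size only. The enterobactin receptor gene fepA was 5.99-fold and the ferrous iron transporter gene feoB 3.75-fold higher, and fhuF had a log2 fold change of -1.07 with TMM and 0.068 with library size only. In the oxidative stress list, 12 of 24 fell, 1 rose and 11 did not pass (median -1.06, but 0.14 with library size only; camera adjusted p = 0.0105; adjusted p = 0.704 with an estimated correlation; the same counts adjusted over the list alone). Here 5 rose and 6 fell with library size only. fldA and ydbK were 19.3-fold and 5.73-fold lower and modA 2.65-fold higher. The OxyR genes of this list, such as ahpF at 935 CPM in cip_6h replicate 3 against 9607 and 6970 CPM in replicates 1 and 2, were far lower in that replicate.

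Flagella and chemotaxis genes were higher in 28 of 51 cases, lower in 2 and not past in 21 (median 1.11, camera adjusted p = 0.00503; adjusted p = 0.704 with an estimated correlation; the same counts adjusted over the list alone). The counts were 42 higher and 0 lower with library size only, and matched lists reached this median (29.7 percentile). The receptor genes aer and tsr were 4.53-fold and 4.40-fold higher, and the receptor gene trg had a log2 fold change of -0.67 with TMM and 0.53 with library size only. The trg call was lost without cip_6h replicate 2 or 3 (adjusted p = 0.0585 and 0.0568; 0.00481 to 0.991 over all alternatives). Of 57 cryptic prophage genes, 29 rose, 3 fell and 25 did not pass (median 1.06, camera adjusted p = 0.00678; adjusted p = 0.301 with an estimated correlation; the same counts adjusted over the list alone). The counts were 45 and 1 with library size only. The median lay at the 1.83 percentile of lists matched on cip_6h level, so the rise of this list did not exceed that of other genes as low. ydaV and stfR were 6.57-fold and 5.64-fold higher and the integrase gene intD 6.33-fold lower. Of 41 toxin-antitoxin genes, 22 rose, 5 fell and 14 did not pass (median 0.87, camera adjusted p = 0.0226; adjusted p = 0.704 with an estimated correlation; the same counts adjusted over the list alone). The counts were 36 and 2 with library size only, and the median lay at the 72.9 percentile of matched lists. dinJ, an antitoxin gene, was 4.23-fold and rnlA 2.67-fold higher, and yafW 7.59-fold lower. The toxin-antitoxin call was lost without amp_24h replicate 1 (adjusted p = 0.0678; 0.00830 to 0.0678 over the alternatives with the preset correlation). hipA, the toxin kinase gene in which persistence mutations were found, was 1.82-fold higher (log2 0.86 ± 0.28 SE, adjusted p = 0.0158). The hipA call was lost without amp_24h replicate 3 or cip_6h replicates 1 or 2 (0.0814, 0.0868 and 0.0630; 5.2e-04 to 0.664 over all alternatives).

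**Figure D2:**
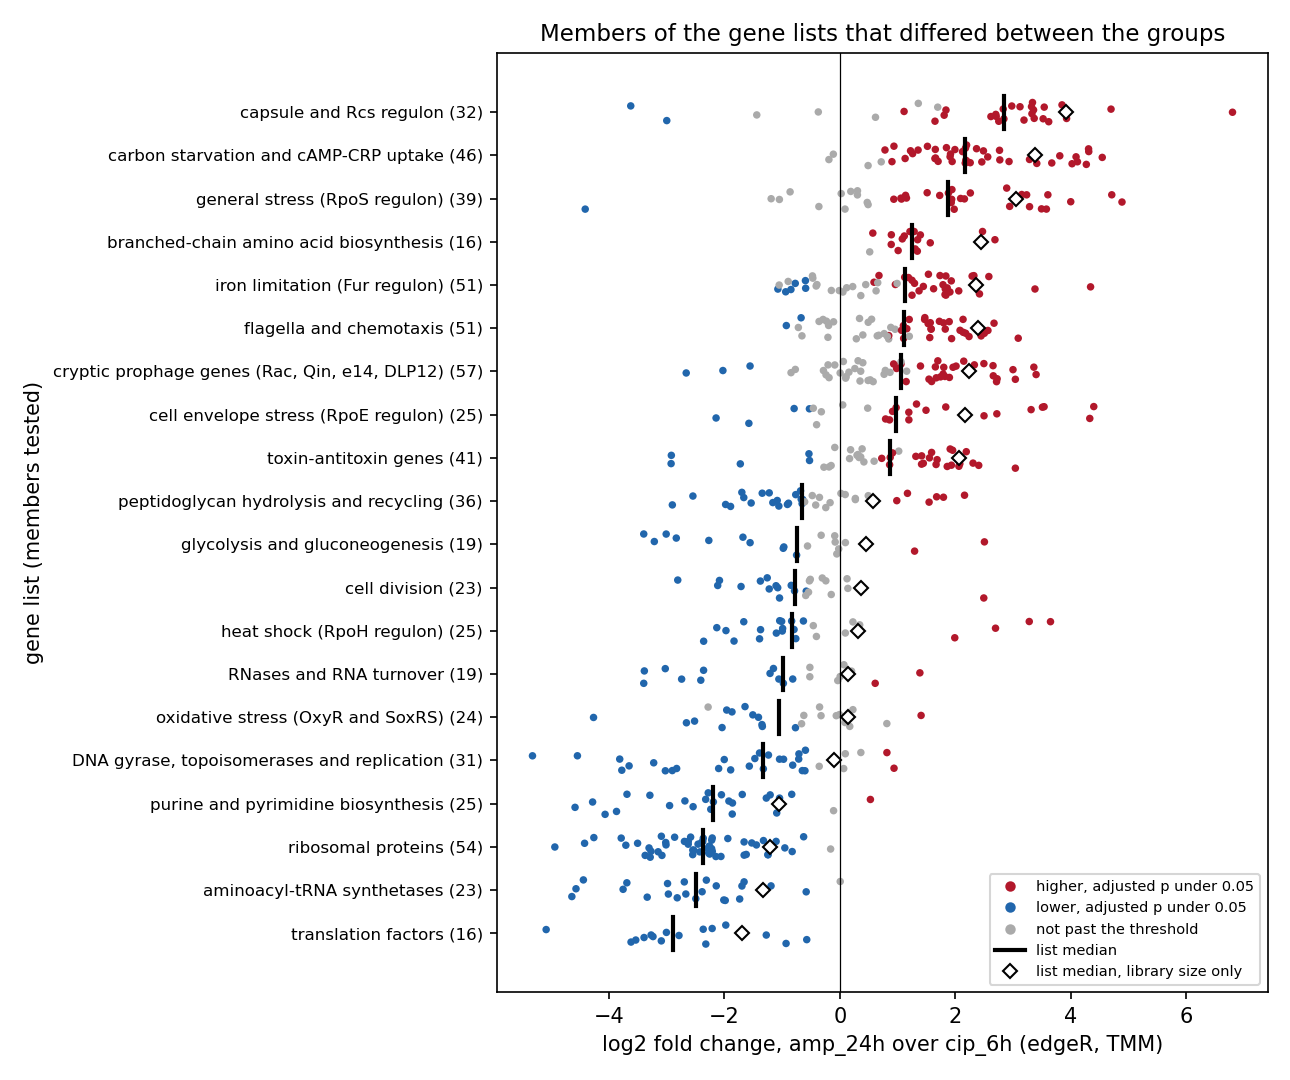
Log2 fold changes (amp_24h over cip_6h) of the tested members of the 20 gene lists that passed camera with a preset correlation; each point is a gene, bars are list medians and diamonds are the medians with library size only. 9 lists were higher and 11 lower, and with library size only the medians of 6 of the lower lists, from oxidative stress at 0.14 to peptidoglycan hydrolysis at 0.57, lay above 0.

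The other lists did not pass camera (preset correlation, p adjusted over the 42 lists), and their counts are given as higher and lower with TMM. Acid resistance genes had 7 and 1 of 14 (median 1.26, adjusted p = 0.0931), and this list passed without cip_6h replicate 3 (0.0321) and with the stricter filter (0.0453), and ranged from 0.0321 to 0.220 over the alternatives with the preset correlation. Cold shock genes had 3 and 7 of 15, with a median of 0.11, a mean of -0.41 and a test in the lower direction (adjusted p = 0.189), and the list passed without amp_24h replicate 1, with a median of -1.19 (0.0463; 0.0463 to 0.401 over the alternatives with the preset correlation). The median was also below 0 with RLE factors (-0.06), the replicate block (-0.83), limma-voom (-0.84), thinned libraries (-0.77) and the stricter filter (-0.67). It was below 0 without any single library except amp_24h replicate 3. Anaerobic respiration and fermentation genes had 23 and 7 of 44 (median 0.74, adjusted p = 0.176), histidine biosynthesis 6 and 0 of 8 (0.80, 0.176), phosphate limitation 16 and 6 of 32 (1.01, 0.244), nitrogen limitation 17 and 12 of 43 (0.58, 0.551), methionine and cysteine biosynthesis 13 and 5 of 27 (0.59, 0.287), and arginine biosynthesis 6 and 6 of 15 (0.48, 0.930). Fimbriae and curli had 3 and 1 of 16 (median 0.51, adjusted p = 0.314). Outer membrane porins had 7 and 7 of 16, with a median of 0.36, a mean of -0.59 and a test in the lower direction (adjusted p = 0.447). Multidrug efflux genes had 13 and 3 of 33 (median 0.49, adjusted p = 0.176), and the main efflux pump gene acrB had a log2 fold change of -0.22 ± 0.24 (SE, adjusted p = 0.431) with TMM, 0.92 with library size only (5.6e-04) and -0.64 without amp_24h replicate 1 (0.00946; 5.6e-04 to 1.00 over all alternatives). Glycerol uptake and use had 8 and 2 of 18 (median 0.10, but -0.06 with RLE factors; adjusted p = 0.227). NADH dehydrogenase and cytochrome oxidases had 8 and 9 of 24 (median -0.40, but 0.82 with library size only and 0.04 with upper quartile factors; adjusted p = 0.594). The TCA cycle had 5 and 5 of 22, with a median of 0.00, -0.14 with RLE factors, a mean of 0.16 and a test in the lower direction (adjusted p = 0.906). ATP synthase had 3 and 1 of 9, with a median of -0.06, 1.04 with library size only, 0.35 with upper quartile factors, a mean of 0.11 and a test in the lower direction (adjusted p = 0.974). Tryptophan biosynthesis and indole had 5 and 5 of 13, with a median of -0.08, 1.08 with library size only, 0.33 with upper quartile factors, a mean of 0.76 and a test in the higher direction (adjusted p = 0.974). Adjusted over the list alone, 12 efflux genes were higher, 7 phosphate genes lower, 2 fimbriae and curli genes higher and 0 lower, and 1 ATP synthase gene higher and 0 lower, and the other lists of this paragraph kept their counts. The counts of this paragraph moved towards higher with library size only, to 13 and 1 for acid resistance, 5 and 3 for cold shock, 36 and 2 for anaerobic respiration and fermentation, 8 and 0 for histidine, 24 and 2 for phosphate and 31 and 1 for nitrogen limitation. In the same setting they were 23 and 1 for methionine and cysteine, 9 and 3 for arginine, 13 and 0 for fimbriae and curli, 9 and 6 for porins, 29 and 2 for efflux and 14 and 2 for glycerol. The respiratory lists had 12 and 1 for NADH dehydrogenase and cytochrome oxidases, 17 and 2 for the TCA cycle and 8 and 0 for ATP synthase there, and tryptophan and indole had 8 and 1.

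Transcripts of the plasmid were a large part of every library. Km took 50.3 ± 2.86% of all counts in amp_24h and 46.5 ± 4.08% in cip_6h (n = 3 per group; exact permutation test, two-sided p = 0.4). The fluorescent protein gene cfp took 6.46 ± 1.70% in amp_24h and 0.106 ± 0.0185% in cip_6h (exact permutation test, two-sided p = 0.1, the smallest this design allows). In the edgeR fit, cfp was 27.7-fold higher in amp_24h (log2 4.79 ± 0.35 SE, adjusted p = 1.3e-07). Km had a log2 fold change of -1.05 ± 0.31 (SE, adjusted p = 0.00857) with TMM and 0.11 with library size only, and its call was lost without amp_24h replicate 3 or cip_6h replicates 1 or 2 (0.0657, 0.0613 and 0.0519; 2.2e-04 to 0.388 over all alternatives). Of 24 genes in the interval deleted in this strain background, 19 had at most 10 counts in every library. The 5 others were cynS, cynX, lacA, lacY and lacZ, named after their values were seen, and lacZ had 230 to 546 counts in amp_24h and 70 to 142 in cip_6h. Of this list, the 5 genes above the filter had 3 higher and 0 lower, also adjusted over the list alone (median 1.47, camera adjusted p = 0.189), and 5 higher and 0 lower with library size only. No genome of the strain or its plasmid was used here, so copies of these 5 genes elsewhere could not be checked.

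**Figure D3:**
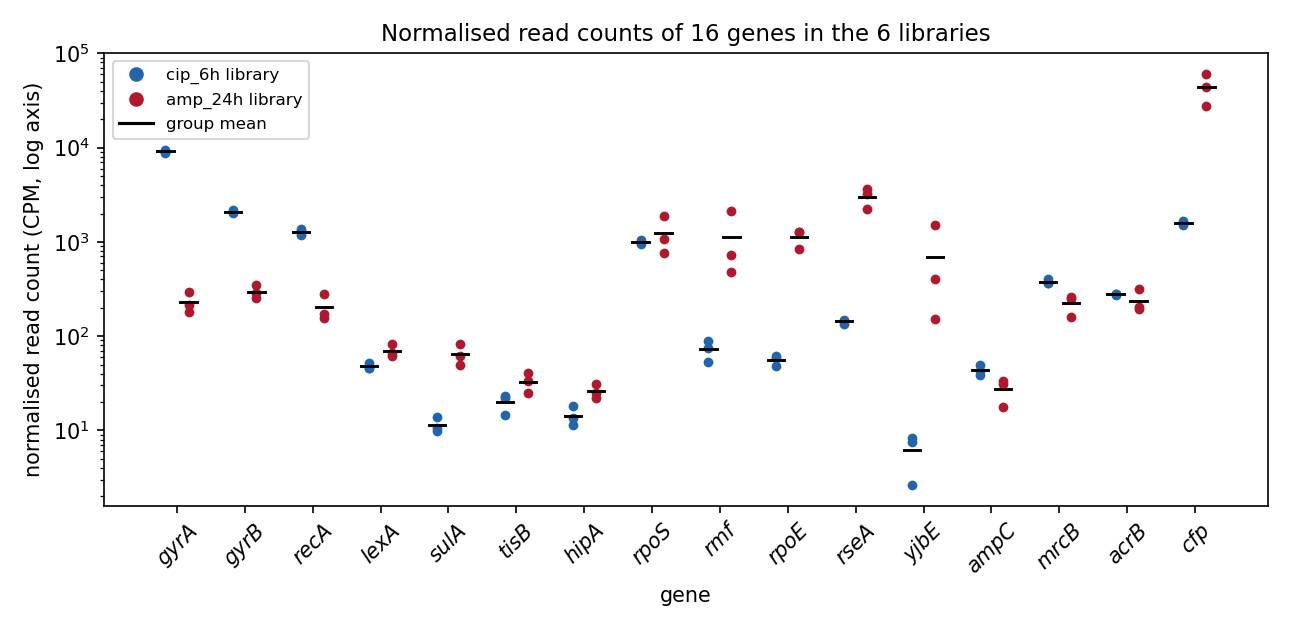
Normalised read counts (CPM, log axis) of 16 genes in the 3 cip_6h and 3 amp_24h libraries; points are libraries and bars are group means. With TMM scaling gyrA was 9156 CPM in cip_6h and 228 CPM in amp_24h on average, and with library size only the differences of ampC, mrcB and acrB turn positive.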

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

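The settings "plasmid genes left out" and "libraries thinned to the lowest chromosomal total" and the counts over other splits were chosen after the results were seen. Between 1519 genes higher and 1234 lower with TMM, the largest moves came with library size only (2668 higher, 492 lower; list members 676 and 171 against 412 and 349) and with the test against a 2-fold change (737 and 689; members 236 and 209), which by construction calls fewer genes. With library size only, 2011 of the 2753 called genes kept their call and direction, and 6 named genes turned, with log2 fold changes of 0.53 for trg, 0.068 for fhuF, 0.57 for ampC, 0.39 for mrcB, 0.92 for acrB and 0.11 for Km. Leaving out the TMM factors moved the median of all genes up by 1.20 (log2). The 6 genes had TMM log2 fold changes from -1.07 (fhuF) to -0.22 (acrB), all smaller in size than this shift. Why the scalings differ this much was not tested. The other settings that kept all libraries gave 1278 to 1980 genes higher and 931 to 1334 lower. Leaving out each library in turn gave 1252 to 1572 higher and 1091 to 1447 lower, 357 to 413 and 311 to 415 list members, and 7 to 10 and 10 to 12 lists. The cfp share difference then ranged from 5.72 to 7.32 percentage points and that of the 100 most abundant genes from -23.7 to -19.6. Thinned libraries gave 1398 and 1134.

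Camera called 9 lists higher and 11 lower with the preset correlation, and with an estimated correlation it called 0 and 0 (4 lists at an unadjusted p under 0.05; smallest adjusted p 0.301), while fry called 17 higher and 15 lower. The cryptic prophage list lost its call although its estimated correlation, -0.012, was below the preset 0.01. A call lost in this setting therefore does not by itself show that correlation between genes undid it. Over all settings, 702 list results kept their side of the threshold, 29 lost a call, 22 gained one and 0 turned in the test's direction while called in either setting. For named genes 1288 kept their side, 51 lost a call and 3 gained one. The 6 that turned had a call in only 1 of the 2 settings, acrB with library size only and the others with TMM. The test's direction is relative to other genes (camera), and the medians of 6 called lists turned with library size only: heat shock 0.31, peptidoglycan hydrolysis 0.57 and cell division 0.36, which lost their calls, and glycolysis 0.45, oxidative stress 0.14 and RNases 0.14, which kept them. The planned setting without rRNA and tRNA genes was not run, since the table lists none, and glmTreat and DESeq2 give no list test.

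The replicate numbers did not pair the samples, since deviations of same-numbered samples correlated at -0.10 to 0.09 across genes and 2 of 6 samples correlated best with their own number. With the replicate number as a block, 1463 genes were higher and 1257 lower.

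The 6 libraries have 10 splits into 3 and 3, too few for a share under 0.05. By edgeR the real split called 2753 genes and the highest other split 0 (3 to 168 at an unadjusted p under 0.05), so 1 of 10 splits reached the real count. For lists, the real split gave 20 and the highest other split 24, so 4 of 10 splits reached the real count. Every other split mixes libraries of both groups on each side. For lists it still carries part of the difference between the groups. For genes it adds that difference to the spread within each side, so neither count measures chance alone. In simulated counts at these depths and this number of libraries, 6.15% of 1.5-fold changes were recovered; which of these limits them was not tested.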

Other observations

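All tests in this part were chosen after the results were seen. Of 5 gene lists added to the fixed ones, 4 changed mostly in 1 direction. All 7 phage shock (psp) genes, which respond to damage of the inner membrane, were higher in amp_24h, with log2 fold changes of 1.52 to 6.12 (median 4.14). Their limma camera p was 8.8e-05 with the preset and 0.0781 with an estimated correlation. pspA stood at 2818 ± 641 CPM in amp_24h and 240.3 ± 64.3 CPM in cip_6h (11.7-fold, n = 3 per group, adjusted p = 4.6e-07), and pspD was 21.1-fold higher. All 13 fatty acid biosynthesis genes were lower, by log2 -4.83 to -2.15 (median -3.06). Their camera p was 4.0e-09 with the preset and 0.131 with an estimated correlation. The enoyl reductase gene fabI was 28.5-fold, fabD 24.8-fold, fabB 20.5-fold and the acyl carrier protein gene acpP 7.79-fold lower. With every scaling tried, each psp gene stayed above 0 and each fatty acid gene below 0. All 11 ribose and galactitol uptake genes were higher (median 4.03). Their limma camera p was 8.4e-07 with the preset and 0.0356 with an estimated correlation. Of 12 SoxRS genes, 8 were lower, 0 higher and 4 not past (median -1.38). Their limma camera p was 0.00155 with the preset and 0.0289 with an estimated correlation. Of 15 OxyR genes, 1 was higher, 1 lower and 13 not past, with a median of -0.40 with TMM, 0.80 with library size only and 0.02 with upper quartile factors. Their limma camera p was 0.899 with the preset and 0.973 with an estimated correlation. The p-values of these 5 lists were not adjusted. The lists were formed from these data, so their tests describe the libraries and give no independent evidence.

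Many genes that were low in cip_6h were higher in amp_24h. Of the genes called higher, 196 had a lowest amp_24h level of at least 10 times the background level (6.64 CPM, the highest library median over the 192 genes under 2 CPM in cip_6h). This count set no limit on the cip_6h level or the length of a gene. It therefore cannot decide on uniform background reads such as residual DNA. Thinning all libraries to the same chromosomal total gave 1398 genes higher against 1519 without thinning, which argues against depth as the whole cause. Misassigned reads or reads from another strain stay open, since 12 genes of the deleted interval had counts in amp_24h (highest per gene 2 to 9) and 0 in every cip_6h library. The count above leaves background reads open for the 196 genes as a set, and they stay open for the other 1323 genes. Fimbriae and curli genes, at a median of 8.52 CPM in amp_24h, had a median at the 1.15 percentile of 10000 lists matched on cip_6h level, but genes this near the floor cannot decide. The drug and the time, which the design names together, may also underlie the pattern and were not tested apart.

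Genes of the OxyR regulon, which answers hydrogen peroxide, were lower in cip_6h replicate 3 than in replicates 1 and 2, with a median deviation of -2.98 (log2, 15 genes), as for katG at 219 against 2989 and 1772 CPM and dps at 48.6 against 1619 and 967 CPM. A swap with an amp_24h library is argued against, since the lowest correlation of this library with its own group exceeded the highest with amp_24h by 0.192 (across genes, which are not independent replicates). Other mislabelling cannot be excluded, since only these groups were compared. Lower depth is argued against as well, since cip_6h replicate 3 held 556765 more chromosomal counts than the shallowest cip_6h library. A general shift of genes at that level is argued against, since the central 95% of 10000 lists matched on abundance deviated by only -0.17 to 0.14. That 0% of these lists lay as low as the OxyR genes adds no support, since the OxyR list was formed from these data. The superoxide (SoxRS) genes deviated by -0.06. A difference in peroxide exposure between these cultures or during their handling is a candidate explanation, and no biological explanation was tested, since the labels give none.

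Capsule and Rcs genes and RpoS genes were higher in amp_24h replicate 1 than in replicates 2 and 3, with median deviations of 1.70 (32 genes) and 0.56 (39 genes). The flatter distribution of counts in the other replicates is argued against as the whole cause. The central 95% of lists matched on abundance deviated by only -0.11 to 0.36 (capsule and Rcs) and -0.21 to 0.26 (RpoS). Both medians lay at the 100 percentile, but this test was chosen after the deviation was seen, and random lists hold genes drawn independently. A swap with a cip_6h library is argued against by a correlation with its own group at least 0.110 above that with cip_6h. Other mislabelling cannot be excluded, since only these groups were compared. No biological explanation was tested, since the labels give no difference between the replicates.

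A hypothesis was tested on position. Across 3968 genes in locus tag order, the log2 fold change fell with distance from the replication origin (Spearman's rho -0.10, Pearson's r -0.10, two-sided p = 0.00655 over all rotations of the gene order). Genes are not independent replicates, and the median was 0.78 in the fifth of genes nearest the origin and 0.14 in the fifth farthest from it. After adjustment for mean abundance rho was -0.19 (p = 0.0166). A difference in gene dose along the chromosome between the populations may contribute, but the effect is small beside the changes of single genes.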
